A study of Arabidopsis thaliana with 12 samples.

How the data were processed

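Gene expression was measured in whole Arabidopsis thaliana seedlings of the wild-type accession Col-0 and of gun1-101, a mutant of GUN1, a pentatricopeptide repeat protein of the chloroplast that takes part in signalling from plastid to nucleus. Per the labels' protocols, seeds were sown on plates with 0.5 mM lincomycin, an inhibitor of plastid translation, or without it. They were stratified for 2 days, exposed to light for 8 h, kept in darkness for 5 days and then moved to continuous light for 2 days, so that seedlings were 7 days old. Total RNA was converted to biotinylated cRNA and hybridised to Affymetrix arrays, per the labels' protocols. The array design is not given in the sources used here.

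The values used are the authors' deposited log2 expression values, made by robust multi-array averaging (RMA) in Affymetrix Expression Console 1.3, per the submitters' processing notes. RMA subtracts background, equalises the distributions of the arrays by quantiles and summarises each probe set, so the deposited values are relative levels on a log2 scale and a change shared by most transcripts would be removed. No further normalisation was applied in the fits reported. Background settings and any batch handling are not given in the sources used here. The number of arrays limits the precision: with 3 arrays per group, the common fit had 8 residual degrees of freedom.

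The table held 38408 probe sets. Of these, 16722 were paired with 1 gene by the platform annotation, 759 with several genes and 20927 with none. A probe set with several genes names no gene here. A probe set without a listed gene is unnamed here, which does not mean that it lacks a gene. Gene identifiers were looked up in a RefSeq gene table of the assembly TAIR10.1, used for names only; 16574 of the probe sets with 1 gene matched it and 148 kept the annotation's own name. After taking the probe set with the highest mean where a gene had more than 1 (146 genes), 16550 genes were tested, of which 1827 carried a symbol and 14723 a locus tag only. The tested genes included 63 of the plastid genome and 17 of the mitochondrial genome. Most nuclear photosynthesis genes of the gene lists lie outside this annotation. Measured were 4 of 21 antenna, 2 of 12 photosystem I, 2 of 11 photosystem II, 3 of 20 Calvin cycle and 7 of 31 tetrapyrrole loci. Counts of list members given below are of measured genes only. Over all hand-written lists, which also cover other processes, 74 of the 457 loci were measured. GUN1 itself is not analysed here, so the level of the mutated gene was not used to check the genotype labels.

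The labels gave 4 groups of 3 arrays, each described as a separate biological replicate. A linear model with 1 mean per group was fitted to all 12 arrays with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, without a replicate block. It gave 5 comparisons: lincomycin against control in each genotype, gun1-101 against Col-0 without and with lincomycin, and the difference of the lincomycin response between genotypes (the interaction). A gene was called when its Benjamini-Hochberg adjusted p over the 16550 genes was under 0.05, two-sided; adjusted p-values given for genes are from this limma fit. The prior standard deviation was 0.204 with 3.89 prior degrees of freedom, and the median residual SD was 0.22. Errors given for log2 differences are standard errors (SE) from this fit.

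The fits, the gene lists, the rule for naming genes and most of the other settings were chosen before the data were examined. Of 32 hand-written lists, 14 had at least 3 measured members and 8 had none. These 14 and 3 lists defined by the organelle genomes were tested with limma's fry, adjusted by Benjamini-Hochberg over the 17 lists of a comparison. The p of fry tests whether the members of a list move, on balance, in 1 direction, and compares the list with no other genes. The 17 lists were light-harvesting antenna, Calvin cycle, photorespiration, tetrapyrrole biosynthesis, plastid ribosomal proteins of the nucleus, plastid chaperones and proteases, mitochondrial dysfunction response, antioxidant enzymes, stomatal lineage and guard cell, reference genes, plastid-encoded photosynthesis genes, plastid-encoded expression genes, cytosolic heat shock, mitochondrion-encoded genes, plastid RNA editing, root markers and anthocyanin. Lists with fewer than 3 measured members were not tested. The name of the cytosolic heat shock list is a label only, as the list also holds HSP15.7 and HSP22.0, small heat shock genes of other compartments. Camera with a preset correlation of 0.01 and with an estimated correlation was an alternative. It compares the members of a list with all other genes, so it asks another question than fry. Every adjusted p of a list given with an estimated correlation is from camera. A list called by fry and not by camera has therefore not lost its call through the correlation alone. The 6 further lists (thylakoid and photosynthesis auxiliary proteins, plastid translation, cytosolic ribosomal proteins, histones, heat response and root hair) and 35 gene families sharing a symbol were assembled after the annotation had been seen, and were adjusted separately.

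Genes were named by a fixed rule. For each comparison it took the 8 highest and 8 lowest log2 differences among called genes that carry a symbol and whose groups do not overlap (no overlap condition for the interaction), up to 4 called members of each list, and a fixed panel of 25 genes, of which PORB was measured. Exceptions, chosen after their values were seen, were 13 genes: AT1G47400, AT1G47395, AT2G14247, AT1G13609, AT2G34620, AT2G18190, AT2G18193, AT3G28570, AT2G04050, AT2G04070, AT4G12490, AT5G62360 and AT5G66150. Members of gene families and of the iron and cold lists named in the closing part were also chosen after their values were seen.

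Other settings fixed in advance were every probe set in place of 1 per gene, the mean of a gene's probe sets, removal of genes under the 25th percentile or the median of mean expression, a shift of each array to a common median, quantile normalisation of the tested genes, an intensity trend with robust eBayes, array weights, a fit to the arrays of the groups compared, the replicate number as a block, and leaving out each of the 12 arrays in turn. Settings chosen after seeing the data were a covariate holding each array's median over the 7083 probe sets that precede the first one with a listed gene, and a fit without Col-0 control replicate 1 and Col-0 lincomycin replicate 3, the array of each Col-0 group with the lowest mean correlation with its group. Leaving out the arrays that correlate least with their group lowers the residual spread, which by itself raises the number of calls. Lists were not tested with an estimated correlation in these added settings.

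The fit was tested on simulated data with the real group sizes and the fitted spread of each gene, in which genes were changed by known amounts, 50 per size. At a log2 change of 1 it recovered 78% for lincomycin in Col-0, 64% for lincomycin in gun1-101, 86% for the genotypes without lincomycin, 78% for the genotypes with lincomycin and 40% for the interaction. At a log2 change of 2 the shares were 100%, 98%, 94%, 100% and 90%, and no recovered gene had the wrong direction. Calls among unchanged genes ranged from 2 for lincomycin in gun1-101 to 11 for lincomycin in Col-0. All other genes were left unchanged, so far fewer genes changed than most real comparisons called. The shares depend on that number through the adjustment of p, so they are not the power of the real comparisons. Overlaps between comparisons were set beside 50 simulations in which both genotypes had the same means. For each treatment that mean was the average of the observed Col-0 and gun1-101 means. The simulated response was thus the average of both genotypes and not that of Col-0. For comparisons that share arrays, the simulated lists were given the observed sizes, taken from the top of each simulated comparison by moderated statistic, a choice made after the data were seen. In all these simulations noise was drawn independently for each gene and array, so shifts shared by many genes of an array were left out. Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots were drawn with matplotlib 3.10.9. Reads, coordinates and sequences were not used here.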

Results

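Transcript levels were measured in 12 arrays of 7-day-old Arabidopsis seedlings, 3 each of Col-0 control, Col-0 with lincomycin, gun1-101 control and gun1-101 with lincomycin. Seedlings had spent 5 days in darkness and 2 days in light, a regime meant to follow chloroplast formation soon after germination, when signalling from plastid gene expression to the nucleus is most active. Array medians over the tested genes lay between 6.59 and 6.70 log2 units. No 2 arrays held identical values. Col-0 control replicate 1 had a mean correlation of 0.979 with the other Col-0 controls and was closest to gun1-101 control replicate 1 (0.992). Mean correlations with the group were 0.9845 and 0.9851 for Col-0 control replicates 2 and 3, 0.9855 for Col-0 lincomycin replicate 3, the lowest of its group, and 0.9887 or more for the other 8 arrays. Over the probe sets that precede the first with a listed gene, the medians were 5.37, 4.50 and 4.50 in the Col-0 controls, 5.07, 5.14 and 4.72 in Col-0 with lincomycin, 5.10, 5.02 and 4.88 in the gun1-101 controls, and 4.71, 4.54 and 4.81 in gun1-101 with lincomycin.

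The comparison of Col-0 with and without lincomycin asked which nuclear and plastid transcripts respond when plastid translation is blocked in the wild type. Nuclear genes of photosynthesis fell. LHCB1.5 (AT2G34420), a light-harvesting protein of photosystem II, fell by 4.36 on the log2 scale (SE 0.25, limma adjusted p = 5.95e-07), a 20.5-fold difference, from 11.70 ± 0.12 to 7.34 ± 0.60 (SD, n = 3). NdhU (AT5G21430), a subunit of the thylakoid NDH complex, fell by 4.16 (SE 0.20, adjusted p = 1.41e-07), from 10.19 ± 0.19 to 6.02 ± 0.46 (SD, n = 3). PORB (AT4G27440), which reduces protochlorophyllide in chlorophyll synthesis, fell by 3.40 (SE 0.15, adjusted p = 7.24e-08), a 10.6-fold difference. The locus AT2G34620, singled out after its values were seen, fell by 5.67 (SE 0.32, adjusted p = 5.77e-07), a 51.0-fold difference.

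**Figure D1:**
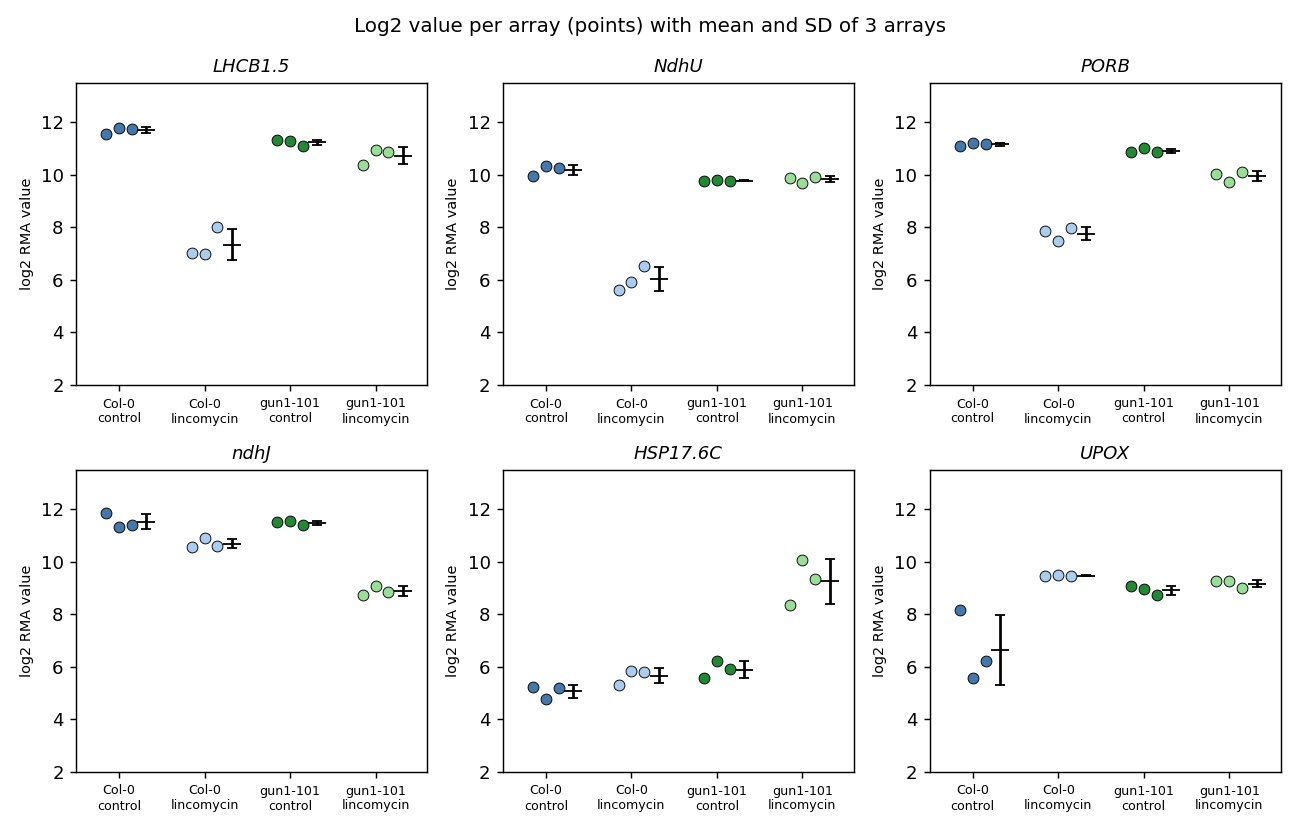
Log2 RMA value (vertical axis) of 6 genes on each array, by group (horizontal axis); points are arrays, and the bar gives mean and SD of 3 arrays. LHCB1.5 lay at 7.34 in Col-0 with lincomycin and 10.73 in gun1-101 with lincomycin, whereas ndhJ lay at 10.69 and 8.89, and the UPOX values of the Col-0 controls were 8.14, 5.56 and 6.22.

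All 4 measured light-harvesting antenna genes fell in Col-0, over all genes and adjusted over the list alone. Their median log2 difference was -2.72 (fry adjusted p = 1.23e-07, and camera adjusted p = 0.0144 with an estimated correlation). LHCB4.2 (-3.81) and LHCB4.1 (-1.63) were among them. All 3 Calvin cycle genes fell on both counts (median -1.71, fry adjusted p = 1.23e-07; adjusted p = 0.0144 with an estimated correlation). The phosphoribulokinase gene PRK fell by 2.82 (SE 0.22), and SBPASE (-1.71) and the Rubisco activase gene RCA (-0.88) fell too. Of 7 tetrapyrrole genes 6 fell, also adjusted over the list alone (median -1.01, fry adjusted p = 3.39e-06; adjusted p = 0.0628 with an estimated correlation). They included the uroporphyrinogen decarboxylase genes HEME1 (-1.72) and HEME2 (-1.44), while HEMA2, a glutamyl-tRNA reductase gene, stood at 0.11. Of 4 photorespiration genes 3 fell on both counts (median -0.98, fry adjusted p = 3.01e-06; adjusted p = 0.0628 with an estimated correlation). The glycine decarboxylase genes GLDH3 (-1.50) and GLDT (-1.11) were the lowest. Of 8 nuclear genes for plastid ribosomal proteins 7 fell on both counts (median -0.92, fry adjusted p = 0.00405; adjusted p = 0.235 with an estimated correlation). The ribosomal gene RPL34 fell by 1.11 (SE 0.13). Among lists with too few members for a test, the photosystem I genes PSAE1 (-3.09) and PSAN (-1.23), the photosystem II genes PSBY (-1.75) and PSBW (-1.21) and the ATP synthase subunit gene ATPC1 (-1.85) fell.

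Of 3 plastid chaperone and protease genes 2 fell on both counts (median -0.50, fry adjusted p = 0.000228; adjusted p = 0.105 with an estimated correlation). In the antioxidant list 1 of 3 genes fell on both counts (median -0.40, fry adjusted p = 0.000246; adjusted p = 0.235 with an estimated correlation), and its median was -0.74 without Col-0 control replicate 1 and Col-0 lincomycin replicate 3 together. It was TAPX, the thylakoid ascorbate peroxidase gene, which fell by 2.22 (SE 0.15). The stomatal list had 2 of 3 genes lower on both counts (median -0.70, fry adjusted p = 0.0277; adjusted p = 0.293 with an estimated correlation). Its call ended without Col-0 control replicate 1 (adjusted p = 0.0508), 2 (0.142) or 3 (0.0809), without Col-0 lincomycin replicate 2 (0.0722) or 3 (0.0653), and without Col-0 control replicate 1 and Col-0 lincomycin replicate 3 together (0.095). Of 31 thylakoid and photosynthesis auxiliary genes, a list added later, 23 fell and none rose, and 27 fell adjusted over the list alone (median -1.003, fry adjusted p = 4.42e-05; adjusted p = 0.071 with an estimated correlation). In the added plastid translation list 3 of 7 genes fell, 4 adjusted over the list alone (median -0.56, fry adjusted p = 4.58e-05; adjusted p = 0.071 with an estimated correlation).

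Outside these lists, the lowest genes in Col-0 taken by the naming rule, which passes over genes without a symbol, were CSLA01 of the mannan synthase family (-4.17, SE 0.27, adjusted p = 1.67e-06), GH3.9 of the auxin-conjugating GH3 family (-3.44, SE 0.22) and the sucrose phosphate synthase gene ATSPS4F (-3.37, SE 0.18). Among those that rose, UPOX, a mitochondrial stress gene, was higher by 2.83 (SE 0.47, adjusted p = 0.00198), M17, a late embryogenesis abundant gene, by 2.43 (SE 0.53, adjusted p = 0.00993) and PAP85, a vicilin-like seed storage gene, by 2.42 (SE 0.34). The chromatin remodeller gene chr31 rose by 1.80, the mitochondrial small heat shock gene HSP23.5 by 1.68 and the sugar transporter gene SWEET4 by 1.68. UPOX stood at 8.14 in Col-0 control replicate 1 against 5.56 and 6.22 in the other Col-0 controls, and M17 at 7.94 against 5.45 and 6.67. In a fit to these 6 arrays alone the adjusted p of M17 was 0.0695. In the mitochondrial dysfunction list 2 of 4 genes rose, 3 adjusted over the list alone (median 1.01, fry adjusted p = 0.0013; adjusted p = 0.105 with an estimated correlation).

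Of 39 photosynthesis genes of the plastid genome 4 fell in Col-0, 3 adjusted over the list alone (median -0.24, fry adjusted p = 0.0628; with the array covariate the list was called, at a median of -0.28 with 6 lower and adjusted p = 0.0391; without Col-0 control replicate 1 and Col-0 lincomycin replicate 3 together the median was -0.11 with 2 lower and adjusted p = 0.333), with ndhJ of the NDH complex lowest at -0.83 (SE 0.16, adjusted p = 0.00525). No gene among 20 plastid-encoded expression genes, which cover ribosomal proteins and polymerase subunits, was called (median -0.14, fry adjusted p = 0.322). The 17 mitochondrion-encoded genes (median 0.11, fry adjusted p = 0.667), 7 RNA editing genes (median -0.04, mean 0.06, fry adjusted p = 0.836) and 3 root markers (median -0.02, fry adjusted p = 0.842) had no call. The 6 genes of the cytosolic heat shock list had a median of 0.51 with 2 higher (fry adjusted p = 0.0754), and 1 of 4 anthocyanin genes fell (median -0.18, fry adjusted p = 0.209). The 3 reference genes, none called singly, shifted upward by a median of 0.18 (fry adjusted p = 0.006; adjusted p = 0.477 with an estimated correlation). Without Col-0 control replicate 1 and Col-0 lincomycin replicate 3 together their adjusted p was 0.095, and the mitochondrion-encoded genes were called (median 0.33, 7 higher, fry adjusted p = 0.0461), whose median with the array covariate was 0.03 (adjusted p = 0.902).

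By limma, 2374 of 16550 genes were called in Col-0, 1184 higher and 1190 lower, and 736 of them by at least 2-fold (251 higher, 485 lower). The split was 940 higher and 1329 lower with each array shifted to the same median, and 1914 and 2372 with every probe set. Without Col-0 control replicate 1 and Col-0 lincomycin replicate 3 together, 4787 were called, 2526 higher and 2261 lower. The count was 1463 without Col-0 control replicate 2, 1512 without Col-0 lincomycin replicate 1 and 1356 without Col-0 lincomycin replicate 2. It was 1067 in a fit to these 6 arrays alone and 4863 with array weights (2670 higher, 2193 lower). The groups did not overlap for 27.4% of genes, against 10% by chance.

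The same question was put to gun1-101, in which a signalling component of the plastid is mutated. Plastid-encoded transcripts fell: 37 of 39 photosynthesis genes were lower, and 39 adjusted over the list alone (median -0.80, fry adjusted p = 0.000352; adjusted p = 0.332 with an estimated correlation). The transcript of ndhJ fell by 2.60 (SE 0.16, adjusted p = 1.11e-05), a 6.05-fold difference, from 11.49 ± 0.08 to 8.89 ± 0.18 (SD, n = 3). Next came psbM (-2.095, SE 0.15), petL (-2.06, SE 0.18) and psaJ (-1.65). Of 20 plastid-encoded expression genes 18 fell, 19 adjusted over the list alone (median -0.66, fry adjusted p = 0.000484; adjusted p = 0.372 with an estimated correlation). They included the ribosomal protein genes rps14 (-2.21, SE 0.17), rpl32 (-1.25) and rps16 (-0.98).

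Heat shock genes rose in gun1-101. Of 6 genes in the cytosolic heat shock list 4 were higher, and 6 adjusted over the list alone (median 2.54, fry adjusted p = 0.000591, and camera adjusted p = 0.332 with an estimated correlation). HSP17.6C (AT1G53540), a small heat shock protein gene, rose by 3.36 (SE 0.35, adjusted p = 0.000165), from 5.89 ± 0.33 to 9.25 ± 0.85 (SD, n = 3), HSP15.7 by 2.74 (SE 0.40), HSP17.8 by 2.57 (SE 0.42) and HSP22.0 by 2.51 (SE 0.27). In the added heat response list 5 of 9 genes rose on both counts (median 1.195, fry adjusted p = 0.0206; adjusted p = 0.521 with an estimated correlation). In Col-0 its median was 0.24 with 2 higher (fry adjusted p = 0.398). The zinc finger gene ZAT7 had the highest named difference, 3.43 (SE 1.05, adjusted p = 0.0389), with arrays at 3.13, 3.45 and 6.16 in the controls and 7.14, 9.25 and 6.63 with lincomycin. The call of ZAT7 ended without Col-0 lincomycin replicate 2 (adjusted p = 0.0515), gun1-101 control replicate 1 (0.126) or 2 (0.122), or gun1-101 lincomycin replicate 1 (0.0735), 2 (0.129) or 3 (0.05). The cold and dehydration genes KIN2 and COR15B rose by 3.03 (SE 0.32) and 2.301 (SE 0.35), and the root transcription factor gene UPB1 by 2.56 (SE 0.33).

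Nuclear photosynthesis genes in gun1-101 were called less widely. Of 4 antenna genes 1 fell on both counts, LHCB4.3 by 0.73 (SE 0.14, adjusted p = 0.00424), and the list median was -0.37 (fry adjusted p = 0.0275; adjusted p = 0.538 with an estimated correlation). Its call ended without gun1-101 control replicate 1 (adjusted p = 0.0639), 2 (0.0752) or 3 (0.0576) or gun1-101 lincomycin replicate 1 (0.191), and its median was -0.57 with the array covariate. LHCB1.5 differed by -0.50 (adjusted p = 0.173), whereas PORB fell by 0.96 (SE 0.15, adjusted p = 0.00136). Of 3 Calvin cycle genes 2 fell on both counts (median -0.72, fry adjusted p = 0.000417; adjusted p = 0.332 with an estimated correlation). Of 4 photorespiration genes 1 fell on both counts (median -0.21, fry adjusted p = 0.0156; adjusted p = 0.571 with an estimated correlation). Its adjusted p was 0.0527 without gun1-101 control replicate 2. Of 3 plastid chaperone and protease genes 1 fell on both counts (median -0.30, fry adjusted p = 0.0166; adjusted p = 0.555 with an estimated correlation). Its adjusted p was 0.0571 and 0.0527 without gun1-101 control replicates 1 and 2. None of 8 plastid ribosomal protein genes was called (median 0.13, fry adjusted p = 0.637). Tetrapyrrole genes went both ways, 1 higher and 2 lower of 7 (median -0.11, fry adjusted p = 0.415), with HEMA2 up by 1.09 (SE 0.17). Thylakoid auxiliary genes had 3 higher and 2 lower of 31 (median 0.10, fry adjusted p = 0.692), and plastid translation genes 1 higher and 1 lower of 7 (median 0.07, fry adjusted p = 0.719).

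Among other genes in gun1-101, CSLA01 fell by 4.69 (SE 0.27, adjusted p = 7.93e-06) and TBL26 fell by 2.66 (SE 0.24). HYH, a light-response bZIP gene, rose by 0.63 (SE 0.13, adjusted p = 0.00587). Of 3 reference genes 1 rose, 2 adjusted over the list alone (median 0.30, fry adjusted p = 0.000591; adjusted p = 0.538 with an estimated correlation). Lists without a call were mitochondrial dysfunction (median 0.52, fry adjusted p = 0.0925), mitochondrion-encoded genes (-0.31, 0.103), antioxidant enzymes (0.71, 0.353), stomatal lineage (0.03, 0.394), RNA editing (-0.02, 0.712), root markers (-0.12, 0.353) and anthocyanin (-0.18, 0.229). With the array covariate the mitochondrial dysfunction list was called (median 0.96, 2 higher, fry adjusted p = 0.0115). Without Col-0 control replicate 1 and Col-0 lincomycin replicate 3 together, calls were gained at the same medians by antioxidant enzymes (fry adjusted p = 0.00807), mitochondrion-encoded genes (0.0204), plastid ribosomal proteins (0.0217) and the added thylakoid list (0.00899). With the covariate these 4 lists were not called (adjusted p = 0.661, 0.25, 0.631 and 0.856), at medians of 0.56, -0.15, -0.11 and -0.03.

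By limma, 3384 genes were called in gun1-101, 1810 higher and 1574 lower, and 945 by at least 2-fold (566 higher, 379 lower). The majority direction turned with each array shifted to the same median (1513 higher, 1905 lower), after quantile normalisation (1540 and 1593) and with every probe set (2636 and 3153). Without Col-0 control replicate 1 and Col-0 lincomycin replicate 3 together, 5141 were called, 2732 higher and 2409 lower. The count was 2221, 2082 and 2247 without gun1-101 control replicates 1, 2 and 3, and 1964 and 2057 without gun1-101 lincomycin replicates 1 and 3. With array weights it was 5682. The groups did not overlap for 45.9% of genes, against 10% by chance.

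**Figure D2:**
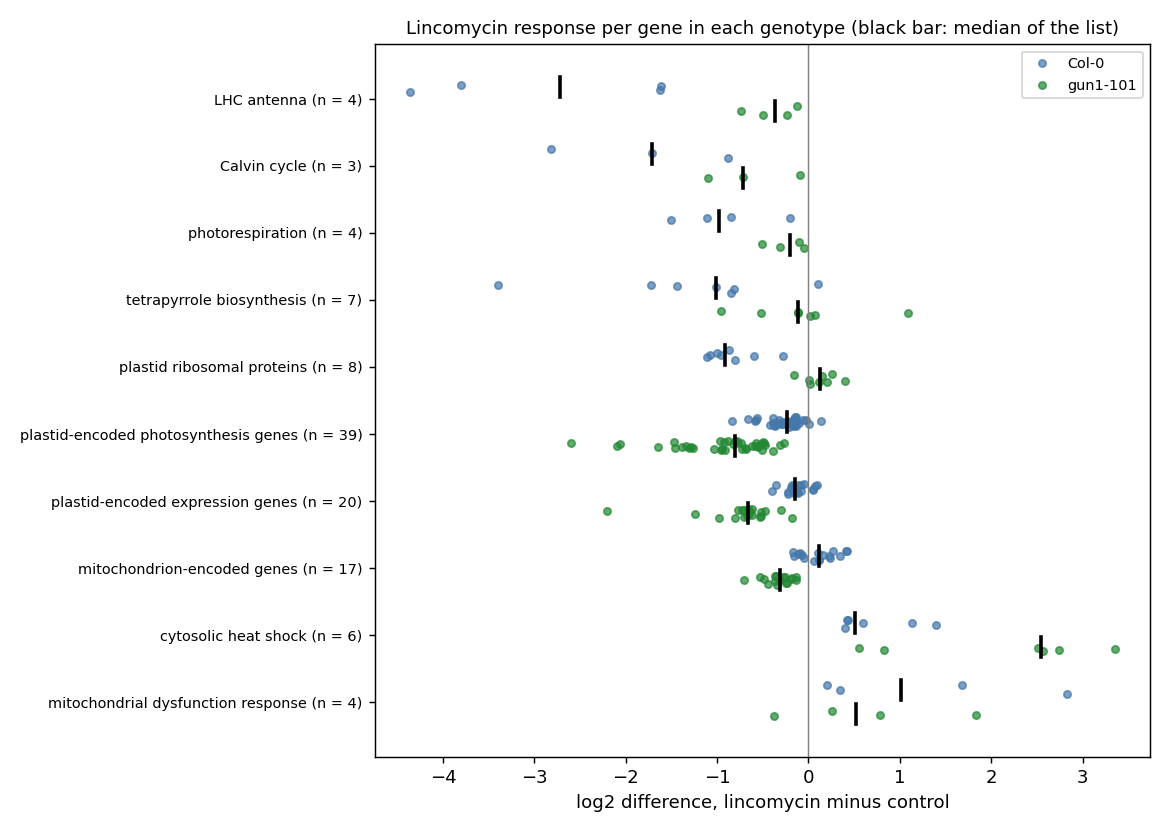
Log2 difference between lincomycin and control (horizontal axis) for each measured gene of 10 lists (vertical axis), in Col-0 (blue) and gun1-101 (green); a black bar marks the list median. Antenna genes had medians of -2.72 in Col-0 and -0.37 in gun1-101, plastid-encoded photosynthesis genes -0.24 and -0.80, and the cytosolic heat shock list 0.51 and 2.54.

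The responses of both genotypes were set side by side over all genes; these comparisons share no arrays. Across 16550 genes, which are not independent replicates, the log2 differences correlated with r = 0.318 and rho = 0.227. Genes higher in both numbered 366, against 129 for independent lists and a mean of 820 in simulations in which both genotypes responded alike. Genes lower in both numbered 397, against 113 and 841. Another 20 genes were higher in Col-0 and lower in gun1-101, and 42 the other way. The loci AT1G47400 (-4.28 in Col-0, -3.33 in gun1-101) and AT1G47395 (-4.25 and -3.41), genes of short peptides of the iron-deficiency response that were chosen after their values were seen, fell in both genotypes.

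The comparison of the untreated genotypes asked what the mutation alone changed. Hsp70-2 (AT5G02490), a cytosolic chaperone gene, was higher in gun1-101 by 2.27 (SE 0.24, limma adjusted p = 0.00934), a 4.83-fold difference, at 8.31 ± 0.09 against 6.03 ± 0.18 (SD, n = 3). The other called genes, named after their values were seen, were AT5G66150, higher by 1.32 (SE 0.16, adjusted p = 0.0219), and AT5G62360, with a log2 difference of -1.53 (SE 0.19, adjusted p = 0.0219). PORB differed by -0.25 (adjusted p = 0.47). The mitochondrial dysfunction list was the only one of 17 called (median 0.76, fry adjusted p = 0.0498; adjusted p = 0.249 with an estimated correlation), with 0 of 4 genes called over all genes and 2 higher adjusted over the list alone. Antenna genes (median -0.30, fry adjusted p = 0.389), tetrapyrrole genes (-0.22, 0.305), plastid-encoded photosynthesis genes (0.03, 0.959), RNA editing genes (0.28, 0.0552) and the cytosolic heat shock list (0.80, 0.254) were not called.

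By limma, 3 genes were called between the untreated genotypes, 2 higher and 1 lower (66.7% higher, against 50% after quantile normalisation), while 2105 had an unadjusted p under 0.05. The count was 1054 without Col-0 control replicate 1 and 2854 without this array and Col-0 lincomycin replicate 3 together, 1216 higher and 1638 lower, and it was 1998 with array weights (856 higher, 1142 lower). It was 5 without Col-0 lincomycin replicate 3, 1 without Col-0 lincomycin replicate 2 or gun1-101 lincomycin replicate 2, and 0 without Col-0 control replicate 2 or 3 or any of the gun1-101 control replicates 1, 2 and 3. The call of Hsp70-2 ended in these last 5 fits, with adjusted p between 0.0686 and 0.0944. Those of AT5G66150 and AT5G62360 ended in them and without either lincomycin replicate 2, with adjusted p up to 0.19 and 0.18, as well as with every probe set and in a fit to these 6 arrays. The mitochondrial dysfunction call ended without Col-0 control replicate 2 (adjusted p = 0.186) or 3 (0.236), Col-0 lincomycin replicate 2 (0.061) or 3 (0.074), gun1-101 control replicate 1 (0.222), 2 (0.0768) or 3 (0.0787) and gun1-101 lincomycin replicate 2 (0.0749) or 3 (0.065). With the replicate number as a block this list call ended as well, and 1 of the 3 gene calls was kept. Without the 2 arrays together 7 lists were called: plastid ribosomal proteins (median -0.42, 5 lower, fry adjusted p = 0.000325), antenna (-0.36, 0.0471), tetrapyrrole (-0.28, 0.0141) and antioxidant genes (-0.44, 0.0101) below 0, and RNA editing (0.32, 0.0106), mitochondrion-encoded (0.35, 0.0182) and mitochondrial dysfunction genes (0.78, 0.000325) above 0. Of the 6 added lists 4 also passed there: thylakoid (median -0.35, 16 of 31 lower, fry adjusted p = 0.000147), core histones (-0.80, 6 of 7 lower, 0.000251), cytosolic ribosomal proteins (-0.38, 28 of 55 lower, 0.000487) and plastid translation (median 0.02 and mean -0.12, 2 lower and 1 higher of 7, tested as lower, 0.0319). Removal of the 2 arrays left the Col-0 controls with unlisted medians of 4.50 and 4.50, against 4.88 to 5.10 in the gun1-101 controls. The untreated genotypes were then also separated by the array covariate, so the gained calls cannot be told apart from the array-wide shift. With the array covariate only the mitochondrial dysfunction list was called of the 17 (median 0.80, fry adjusted p = 0.0156) and none of the 6 added lists, the lowest adjusted p among which was 0.0857.

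The comparison of the genotypes on lincomycin asked which transcripts depend on GUN1 when plastid translation is blocked. Nuclear photosynthesis genes were higher in gun1-101. NdhU was higher by 3.81 (SE 0.20, limma adjusted p = 5.57e-07), at 9.83 ± 0.12 against 6.02 ± 0.46 (SD, n = 3), LHCB1.5 by 3.39 (SE 0.25, adjusted p = 1.03e-05), LHCB4.2 by 3.15 (SE 0.22) and PORB by 2.19 (SE 0.15, adjusted p = 6.06e-06). All 4 antenna genes were higher, over all genes and adjusted over the list alone (median 2.24, fry adjusted p = 1.88e-06; adjusted p = 0.0166 with an estimated correlation). All 3 Calvin cycle genes were also higher on both counts (median 1.00, fry adjusted p = 2.51e-06; adjusted p = 0.0204 with an estimated correlation). PRK differed by 1.90 and SBPASE by 1.00. Of 7 tetrapyrrole genes 6 were higher, 7 adjusted over the list alone (median 0.74, fry adjusted p = 2.4e-05; adjusted p = 0.0629 with an estimated correlation). HEME1 was higher by 1.46 and HEME2 by 1.13. Of 4 photorespiration genes 3 were higher on both counts (median 0.69, fry adjusted p = 2.4e-05; adjusted p = 0.0635 with an estimated correlation). Plastid ribosomal protein genes had 3 of 8 higher, 8 adjusted over the list alone (median 0.64, fry adjusted p = 0.00952; adjusted p = 0.171 with an estimated correlation). With the array covariate 2 were higher, 3 adjusted over the list alone (median 0.40, fry adjusted p = 0.0102). The added thylakoid list had 23 of 31 higher, 27 adjusted over the list alone (median 0.87, fry adjusted p = 8.94e-05; adjusted p = 0.0472 with an estimated correlation). The added plastid translation list had 2 of 7 higher, 5 adjusted over the list alone (median 0.45, fry adjusted p = 9.15e-05; adjusted p = 0.0472 with an estimated correlation).

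Heat shock genes and the cold and dehydration gene COR15B (AT2G42530) were also higher in gun1-101 on lincomycin. COR15B was higher by 4.66 (SE 0.35, adjusted p = 1.07e-05), a 25.4-fold difference, at 8.69 ± 0.33 against 4.02 ± 0.32 (SD, n = 3). Of 6 genes in the cytosolic heat shock list 5 were higher, 6 adjusted over the list alone (median 2.02, fry adjusted p = 0.000579, and camera adjusted p = 0.0635 with an estimated correlation). HSP17.6C was higher by 3.59 (SE 0.35), HSP17.8 by 2.91 and HSP15.7 by 2.36. Of 9 genes in the added heat response list 6 were higher, 8 adjusted over the list alone (median 1.47, fry adjusted p = 0.00129; adjusted p = 0.0472 with an estimated correlation). The MADS-box gene AGL87 was higher by 2.51 (SE 0.39) and the isocitrate lyase gene ICL by 1.66 (SE 0.27). The locus AT4G12490, chosen after its values were seen, was higher by 3.94 (SE 0.63, adjusted p = 0.00248).

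Plastid-encoded transcripts were lower in gun1-101 on lincomycin. Of 39 photosynthesis genes 28 were lower, 36 adjusted over the list alone (median -0.55, fry adjusted p = 0.000641; adjusted p = 0.159 with an estimated correlation). The log2 difference was -1.80 for ndhJ (SE 0.16, adjusted p = 4.22e-05), -1.73 for petL and -1.59 for psbM. Of 20 expression genes 13 were lower, 17 adjusted over the list alone (median -0.59, fry adjusted p = 0.000745; adjusted p = 0.16 with an estimated correlation). Among them rps14 stood at -1.73. Among nuclear genes, chr31 was lower at -1.95 (SE 0.18, adjusted p = 4.22e-05) and APL3, for a large subunit of ADP-glucose pyrophosphorylase, at -1.65 (SE 0.29). Antioxidant genes had 2 of 3 higher on both counts (median 0.79, fry adjusted p = 0.000641; adjusted p = 0.0991 with an estimated correlation). Chaperones and proteases had 0 of 3 higher, 2 adjusted over the list alone (median 0.43, fry adjusted p = 0.00235; adjusted p = 0.159 with an estimated correlation). Reference genes had 0 of 3 higher (median 0.21, fry adjusted p = 0.00768; adjusted p = 0.4 with an estimated correlation). The stomatal list had 1 of 3 higher, 2 adjusted over the list alone (median 0.67, fry adjusted p = 0.00952; adjusted p = 0.159 with an estimated correlation). Its adjusted p was 0.0522 without Col-0 control replicate 1 and Col-0 lincomycin replicate 3 together.

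RNA editing genes had 1 of 7 higher, 2 adjusted over the list alone (median 0.12, fry adjusted p = 0.0387; adjusted p = 0.209 with an estimated correlation). That call ended without Col-0 control replicate 2 (adjusted p = 0.0551) or 3 (0.0532), Col-0 lincomycin replicate 2 (0.125) or 3 (0.134), gun1-101 control replicate 1 (0.0509) or 2 (0.052) and gun1-101 lincomycin replicate 1 (0.0519), 2 (0.0634) or 3 (0.112). It also ended without the 2 arrays together (0.0682), and the median was 0.27 with the array covariate (adjusted p = 0.00626). Mitochondrial dysfunction (median 0.26, fry adjusted p = 0.394), mitochondrion-encoded genes (-0.15, 0.342), root markers (-0.08, 0.666) and anthocyanin (-0.20, 0.666) had no call.

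By limma, 1585 genes differed between the genotypes on lincomycin, 848 higher and 737 lower in gun1-101, and 551 by at least 2-fold (403 higher, 148 lower). Without Col-0 control replicate 1 and Col-0 lincomycin replicate 3 together, 4088 were called, 2038 higher and 2050 lower, and with array weights 4385, 2150 higher and 2235 lower. The count was 806, 748 and 2464 without Col-0 lincomycin replicates 1, 2 and 3, and 951 and 826 without gun1-101 lincomycin replicates 1 and 3. The groups did not overlap for 30.5% of genes, against 10% by chance. Of the 1190 genes lower with lincomycin in Col-0, 444 (37.3%) were higher in gun1-101 than in Col-0 on lincomycin, against 61.0 for independent lists. In 50 simulations without an effect of genotype, lists of the same sizes from the top of each comparison shared 140 genes on average and 163 at most. Of the 1184 genes higher in Col-0, 180 (15.2%) were lower in gun1-101, against 52.7 for independent lists and, in the simulations, 135 on average and 158 at most. Both comparisons use the Col-0 lincomycin arrays, so part of the excess can come from the shared arrays. The simulations held no array-wide shifts, so their highest values may be too low.

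The last comparison asked whether the lincomycin response itself differed between the genotypes. It did for photosynthesis genes: the difference, gun1-101 minus Col-0, was 4.22 for NdhU (SE 0.28, limma adjusted p = 1.08e-05), 3.86 for LHCB1.5 (SE 0.35, adjusted p = 0.000149), 3.57 for LHCB4.2 (SE 0.32, adjusted p = 0.00011), 2.89 for PSAE1 and 2.44 for PORB (SE 0.21, adjusted p = 8.97e-05). All 4 antenna genes were positive, also adjusted over the list alone (median 2.54, fry adjusted p = 1.46e-05; adjusted p = 0.0341 with an estimated correlation). So were all 3 Calvin cycle genes (median 0.99, fry adjusted p = 4.12e-05; adjusted p = 0.0552 with an estimated correlation). Tetrapyrrole genes had 6 of 7 positive, 7 adjusted over the list alone (median 0.99, fry adjusted p = 9.72e-05; adjusted p = 0.0868 with an estimated correlation). Photorespiration had 2 of 4 positive, 3 adjusted over the list alone (median 0.67, fry adjusted p = 0.000329; adjusted p = 0.136 with an estimated correlation). Plastid ribosomal proteins had 3 of 8 positive, 8 adjusted over the list alone (median 0.98, fry adjusted p = 0.0146; adjusted p = 0.26 with an estimated correlation). With the array covariate 1 was positive, 3 adjusted over the list alone (median 0.55, fry adjusted p = 0.0304). The added thylakoid list had 21 of 31 positive, 27 adjusted over the list alone (median 1.15, fry adjusted p = 0.000296; adjusted p = 0.0737 with an estimated correlation). The added plastid translation list had 2 of 7 positive on both counts (median 0.61, fry adjusted p = 0.00061; adjusted p = 0.13 with an estimated correlation). Antioxidant genes had 2 of 3 positive on both counts (median 1.12, fry adjusted p = 0.00216; adjusted p = 0.136 with an estimated correlation).

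Plastid-encoded genes had the opposite sign in this comparison. Of 39 photosynthesis genes 13 were negative, 32 adjusted over the list alone (median -0.59, fry adjusted p = 0.00554; adjusted p = 0.26 with an estimated correlation). Of 20 expression genes 6 were negative, 14 adjusted over the list alone (median -0.56, fry adjusted p = 0.00681; adjusted p = 0.281 with an estimated correlation). The lowest of these were rps14 (-1.80), ndhJ (-1.76), petL (-1.73) and psbM (-1.53). With the array covariate 5 photosynthesis and 2 expression genes were negative, and without Col-0 control replicate 1 and Col-0 lincomycin replicate 3 together 31 and 13. COR15B had a difference of 4.00 (SE 0.49), TRY, a trichome patterning gene, of 3.07 (SE 0.45, adjusted p = 0.00303) and AGL87 of 3.06 (SE 0.55). M17 (-2.81, SE 0.75, adjusted p = 0.045) and UPOX (-2.57, SE 0.66, adjusted p = 0.04) were the most negative named genes. In untreated gun1-101 UPOX already stood at 9.06, 8.95 and 8.72, against 9.25, 9.25 and 9.01 there with lincomycin. M17 stood at 8.84, 8.77 and 8.72 in untreated gun1-101, against 8.29, 8.64 and 8.25 there with lincomycin. In Col-0 with lincomycin UPOX reached 9.44, 9.49 and 9.48, and M17 9.76, 9.51 and 8.08. Both calls ended without Col-0 control replicate 2 or 3, Col-0 lincomycin replicate 1 or 2, or any single gun1-101 array, with adjusted p between 0.0673 and 0.115 for M17 and between 0.0672 and 0.0944 for UPOX, and with the array covariate (0.12 and 0.0849) or every probe set (0.07 and 0.0641).

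The cytosolic heat shock list had a median difference of 1.36 with 2 of 6 positive, 3 adjusted over the list alone (fry adjusted p = 0.0401, and camera adjusted p = 0.26 with an estimated correlation). That call ended with the array covariate (0.0992), without Col-0 control replicate 1 and Col-0 lincomycin replicate 3 together (0.109), and without any 1 array except gun1-101 lincomycin replicates 1 and 2, with adjusted p between 0.0575 and 0.0905. The stomatal list had 0 of 3 positive, 2 adjusted over the list alone (median 0.79, fry adjusted p = 0.0249; adjusted p = 0.26 with an estimated correlation). Its call ended without Col-0 control replicate 2 (adjusted p = 0.0673), Col-0 lincomycin replicate 2 (0.062) or gun1-101 control replicate 3 (0.0649) or lincomycin replicate 3 (0.0652), and with the array covariate (0.0612). Mitochondrial dysfunction (median -0.29, fry adjusted p = 0.0786), mitochondrion-encoded genes (-0.41, 0.11), reference genes (0.12, 0.199), chaperones and proteases (0.20, 0.0843), root markers (-0.10, 0.349), RNA editing (-0.17, 0.639), anthocyanin (-0.12, 0.953) and the added heat response list (0.52, 0.0855) were not called. Without the 2 arrays together the first 4 of these were called: mitochondrial dysfunction (median -0.29, fry adjusted p = 0.000977), mitochondrion-encoded genes (-0.66, 9 of 17 negative, 0.00607), reference genes (0.12, 0.0165) and chaperones and proteases (0.18, 0.0134). These 4 were not called with the array covariate (adjusted p = 0.0992, 0.396, 0.488 and 0.151), and the mitochondrion-encoded median was -0.19.

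By limma, the response differed for 1153 genes, 664 with a positive and 489 with a negative difference, and for 763 by at least 2-fold (498 and 265). Without Col-0 control replicate 1 and Col-0 lincomycin replicate 3 together the count was 5378 (2645 and 2733), with array weights 5536 (2669 and 2867), and with the array covariate 527 (345 and 182). It moved with each array left out: to 3876, 435 and 476 without Col-0 control replicates 1, 2 and 3, to 435, 379 and 2986 without Col-0 lincomycin replicates 1, 2 and 3, to 567, 509 and 522 without gun1-101 control replicates 1, 2 and 3, and to 504, 704 and 424 without gun1-101 lincomycin replicates 1, 2 and 3. Of the 1190 genes lower with lincomycin in Col-0, 394 (33.1%) had a positive difference, against 47.7 for independent lists and, with lists of the same sizes in the simulations, 145 on average and 168 at most. Part of this excess can come from the shared Col-0 arrays, whose array-wide shifts the simulations did not include.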

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

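Tests chosen only after their result was seen were the wrong genotype label and the label swap of Col-0 control replicate 1, the loss of plastid RNA as a whole and the handling of the gun1-101 plates; the array covariate and the fit without 2 arrays were added after the data were seen, while the tests of the array-wide shift were set before their result.

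The lincomycin response differed between Col-0 and gun1-101 by the interaction test for 1153 genes and for 10 of 17 lists. List medians of that difference were 2.535 for antenna genes, 1.364 for cytosolic heat shock, 1.116 for antioxidant enzymes, 0.991 for the Calvin cycle, 0.987 for tetrapyrrole biosynthesis, 0.976 for plastid ribosomal proteins, 0.793 for the stomatal lineage, 0.67 for photorespiration, -0.562 for plastid-encoded expression genes and -0.586 for plastid-encoded photosynthesis genes. Camera with an estimated correlation, which compares a list with all other genes, called 1 of these 10 lists, the antenna genes (adjusted p = 0.0341). With the array covariate the heat shock and stomatal calls by fry ended (fry adjusted p = 0.0992 and 0.0612). The same test singled out NdhU (4.22), COR15B (3.998), LHCB1.5 (3.855), LHCB4.2 (3.572), TRY (3.072), AGL87 (3.056), PSAE1 (2.889) and HSP17.6C (2.763) above 0. Below 0 it singled out M17 (-2.81), UPOX (-2.567), APL3 (-1.888), scpl16 (-1.852), rps14 (-1.803), chr31 (-1.781), ndhJ (-1.764) and SCPL15 (-1.752). The call of APL3 ended without Col-0 control replicate 2 (adjusted p = 0.0607), Col-0 lincomycin replicate 1 (0.0644) or 2 (0.0663), gun1-101 control replicate 1 (0.0525) or gun1-101 lincomycin replicate 3 (0.0603), and that of scpl16 without Col-0 lincomycin replicate 2 (0.0585). Of 100 draws of the genotype labels within each treatment, 1, the real one, called as many genes, and the highest other called 381. The other draws also mix the genotypes on lincomycin, where 1585 genes differed, and that effect then adds to the spread. The draws thus argue against labels without any genotype effect, and cannot decide on the interaction alone.

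Probe sets without a listed gene, which the comparisons of genes leave out, were also called. By limma over these 20927 probe sets, lincomycin raised 907 in Col-0 and lowered 1263, and raised 1111 in gun1-101 and lowered 1791, each against the controls of the same genotype. Between the genotypes 4 differed without lincomycin and 1319 with it.

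The first pattern weighed is Col-0 control replicate 1, which stood apart from the other Col-0 controls and whose removal moved the untreated genotype comparison from 3 to 1054 genes. An array-wide shift that also moves probe sets without a listed gene may account for part of it, since its deviation correlated at r = 0.553 across 16550 genes with the slope estimated in the 9 arrays of the other groups, whereas a label swap with Col-0 lincomycin replicate 3 is argued against, since over 679 lincomycin genes its median position was 0.066 (bootstrap interval 0.036 to 0.094) from the other Col-0 controls at 0 to the other Col-0 lincomycin arrays at 1, and the proposed partner lay at 0.981. A wrong genotype label is at most weakly argued against as the whole cause, and the verdict was set after the values were seen. At 28 genes that separate the genotypes, its position with the shift removed was 0.307 (0.019 to 0.455). On that scale the other Col-0 controls are at 0 and the gun1-101 controls at 1. Other controls were held out in turn, each placed by its own 28 genes and on its own scale. The gun1-101 controls then lay at 0.737 to 0.988 (lowest lower bound 0.621), and the other Col-0 controls at 0.161 and 0.403. The slope used for the removal came from arrays with unlisted medians up to 5.14, so it was extrapolated to this array at 5.37. Without removal of the shift the values decide less: its position was 0.45 (0.286 to 0.647), with an upper bound over the 0.5 set for excluding the label, against 0.697 to 0.976 (lowest lower bound 0.647) and 0.126 and 0.347. Over all 1054 genes that separate the controls without this array it was 0.939, and 0.427 (0.389 to 0.473) with the shift removed, so what else sets it between the groups stays open, and no biological explanation was tested, as the design gives none for a single replicate.

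The second pattern is the further fall of plastid-encoded transcripts in gun1-101. The array-wide shift is argued against as its whole cause: with the covariate the median difference over 39 photosynthesis genes was -0.465 (quartiles -0.712 to -0.354). A loss of plastid RNA as a whole in gun1-101 with lincomycin could account for it, since the plastid-encoded expression genes also fell there, by a median log2 difference of -0.66 (quartiles -0.735 to -0.529). As a hypothesis, gun1-101 may accumulate fewer plastid transcripts when plastid translation is blocked; whether transcription, stability or plastid number is involved was not tested.

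The third pattern is the higher level of heat shock genes in gun1-101 on lincomycin. The array-wide shift is argued against, as the median difference with the covariate was 1.975 (limma's fry adjusted p = 0.00217). Handling of the gun1-101 plates that differed from that of Col-0 stays possible, since the list median was also 0.804 higher in the untreated mutant (limma's fry adjusted p = 0.254). An effect of the genotype itself may give the same values and stays open.

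With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. For lincomycin in Col-0 the real split called 2374 genes and the highest other 2288; that other split, with Col-0 control replicate 1 and Col-0 lincomycin replicates 1 and 2 on 1 side, follows the medians of the unlisted probe sets, and with these as a covariate 2825 genes were called. For lincomycin in gun1-101 the real split called 3384 and the highest other 0, and for the genotypes on lincomycin 1585 and 0. For the untreated genotypes 2 of the 10 splits called 3 genes, the highest other setting Col-0 control replicate 1 with gun1-101 control replicates 1 and 2, and with the covariate 3 genes were called.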

How the results depend on the processing

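The array covariate and the fit without 2 arrays were chosen after the data were seen; the other settings were planned. No named gene or list call reversed direction in the settings in which it was tested. For lists these were leaving out an array, the replicate block, the covariate and the fit without 2 arrays. Of 281 named gene results 186 kept their call in every planned setting that gave a value, and of 42 list results 34. Named calls ended for 36 with every probe set, 35 of 216 in fits to the groups compared, 39 with the covariate, 9 with quantile normalisation, 4 with the median shift and 518 of 3372 when 1 array was left out; list calls ended in 44 of 504 such fits. The cause was not tested, except that leaving out arrays or groups lowers the degrees of freedom and that every probe set raises the number of tests. The number of arrays limits the precision, and no detection call was used, so the level at which signal exceeds background was not set.

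With every probe set tested, 4286 were called for lincomycin in Col-0, 5789 in gun1-101, 5 for the untreated genotypes and 2582 on lincomycin. In fits to the groups compared the Col-0 count was 1067. Array weights (0.272 for Col-0 control replicate 1, 0.376 for Col-0 lincomycin replicate 3) gave 4863, 5682, 1998, 4385 and 5536. Genes above the median gave 1 for the untreated genotypes. The fit without 2 arrays dropped those that correlated least with their group, which by itself raises the counts. Without 2 arrays together the counts were 4787, 5141, 2854, 4088 and 5378, and 2075 of 2374, 3371 of 3384, 3 of 3, 1549 of 1585 and 1149 of 1153 calls were kept; the covariate gave 527 for the interaction. Leaving out 1 array gave 1356 to 3377, 1964 to 4289, 0 to 1054, 748 to 2464 and 379 to 3876; beside the 0, 2105 genes had an unadjusted limma p under 0.05 with all arrays. Called lists ranged from 9 to 12, 5 to 10, 0 to 2, 12 to 13 and 8 to 11. Camera with an estimated correlation called 2, 0, 0, 2 and 1 lists against 10, 8, 1, 13 and 10 by fry; with the preset correlation it called 4 for lincomycin in gun1-101 and 6 for the untreated genotypes, and without 2 arrays fry called 7 there.

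The replicate numbers are shared by the groups, but whether they pair the arrays could not be settled. Of 18 same-numbered pairs 7 had r over 0.1 (range -0.298 to 0.439), and 6 of 12 arrays were closest to one of their own number. With the replicate block 2468, 3450, 1, 1669 and 1368 genes and 9, 8, 0, 13 and 9 lists were called; for the untreated genotypes 1 of the 3 gene calls was kept.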

Other observations

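The families described here were picked after all 35 families had been tested, and the 6 added lists were assembled after the annotation was seen; the tests of the iron and cold lists were set before their result was seen.

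In gun1-101, lincomycin raised autophagy genes: 7 of 8 genes with an ATG symbol rose (median 1.15, limma's fry adjusted p = 0.00118 over 35 families; adjusted p = 0.228 with an estimated correlation). They included genes of the ATG8 group, which coats the autophagosome membrane: ATG8B rose by 1.51 (SE 0.21, adjusted p = 0.000773), ATG8H by 1.41 (SE 0.19), ATG8G by 1.29 and ATG8E by 1.16, while ATG8F stood at 0.12 (adjusted p = 0.445). Of 15 ubiquitin-conjugating enzyme genes 8 rose (median 0.46, fry adjusted p = 0.00562; adjusted p = 0.321 with an estimated correlation), and 5 of 9 NRPB genes for RNA polymerase II subunits (median 0.93, or 0.55 with the array covariate, fry adjusted p = 0.016; adjusted p = 0.337 with an estimated correlation). In the same comparison 10 of 17 IQD genes for calmodulin-binding proteins fell (median -0.47, fry adjusted p = 9.87e-05; adjusted p = 0.11 with an estimated correlation), with iqd21 at -1.35 and IQD24 at -1.15.

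Root hair genes fell with lincomycin in gun1-101, 5 of 9 on the added list (median -0.80, fry adjusted p = 0.0285; adjusted p = 0.521 with an estimated correlation), against 0 of 9 in Col-0 (median 0.03, fry adjusted p = 0.952). The difference of the response was called for the list (median -0.82, fry adjusted p = 0.0408; adjusted p = 0.226 with an estimated correlation). That call ended without Col-0 control replicate 1 and Col-0 lincomycin replicate 3 together (fry adjusted p = 0.32, 2 higher and 4 lower). On lincomycin the genotypes differed by a median of -0.27 (fry adjusted p = 0.136). With the array covariate that median was -0.526 (fry adjusted p = 0.0576). In the same setting the untreated genotypes differed by a median of 0.539 (fry adjusted p = 0.0857), with 4 of 9 genes higher adjusted over the list alone. The difference of the response thus also holds a difference between the controls. Core histone genes fell in Col-0, 3 of 7, or 5 adjusted over the list alone (median -0.78, fry adjusted p = 0.0255; adjusted p = 0.253 with an estimated correlation), and stood at 0.39 in gun1-101 (fry adjusted p = 0.307). The histone response differed between genotypes (median 0.97, fry adjusted p = 0.0156; adjusted p = 0.146 with an estimated correlation), and their difference on lincomycin was 0.47 (fry adjusted p = 0.0885). Of 55 cytosolic ribosomal protein genes 7 fell in Col-0, 6 adjusted over the list alone (median -0.36, fry adjusted p = 0.0259; adjusted p = 0.269 with an estimated correlation); the median was 0.20 in gun1-101 (fry adjusted p = 0.307) and 0.27 between the genotypes on lincomycin (fry adjusted p = 0.0879). The response of that list differed by a median of 0.58 (fry adjusted p = 0.0199; adjusted p = 0.191 with an estimated correlation), a call that ended with the array covariate (median 0.40, fry adjusted p = 0.0614). Without the 2 arrays together the medians of core histones were -1.34 in Col-0 and 1.52 for the difference of the response, that of the cytosolic ribosomal list in Col-0 was -0.62 with 38 of 55 lower, and both lists were also called in gun1-101 (fry adjusted p = 0.00899 for each) and between the genotypes on lincomycin (0.000241 for each). Neither list was called in those comparisons with the array covariate (fry adjusted p = 0.591 for each in gun1-101 and 0.184 for each on lincomycin). The medians of core histones were then 0.063 in gun1-101 and 0.267 on lincomycin, and those of the cytosolic ribosomal list 0.111 and 0.169.

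A hypothesis arose from iron-deficiency genes among the largest falls in both genotypes: AT1G13609 (-6.06 in Col-0, -5.22 in gun1-101), AT2G14247 (-5.53 and -4.70), AT1G47400 and AT1G47395. The iron-deficiency response as a whole may be lower with lincomycin. It was tested with limma's fry on 15 measured genes of that response that had not been seen, with p adjusted over 10 tests of the iron and cold lists. The higher of the 2 medians was -0.241, in gun1-101 (5 of 15 lower, adjusted p = 0.0118; adjusted p = 0.197 with an estimated correlation), and the median in Col-0 was -1.03 (10 of 15 lower, adjusted p = 0.000115; adjusted p = 0.0309 with an estimated correlation). The unseen AT5G38820 stood at -2.66 and -2.19. The difference of the response over the 15 genes was called by fry, with a smaller fall in gun1-101 (median 0.406, fry adjusted p = 0.033). With an estimated correlation its adjusted p was 0.152, and 0 of the 15 genes were called singly.

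A further hypothesis is that the cold and dehydration response rises as a whole with lincomycin in gun1-101, since COR15B and KIN2 were among the highest. Over 4 measured genes not seen before, the median was 0.805 (2 higher, fry adjusted p = 0.00472; adjusted p = 0.152 with an estimated correlation), with COR47 at 1.14. In Col-0 the median was 0.47 (fry adjusted p = 0.0358; adjusted p = 0.249 with an estimated correlation). Between the genotypes on lincomycin it was 0.47 with 0 of 4 genes called (fry adjusted p = 0.0144; adjusted p = 0.152 with an estimated correlation). The difference of the response was not called (fry adjusted p = 0.196), so whether the rise differs between the genotypes stays open.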
